A study of environmental samples and uncultured sulfate-reducing bacterium with 83 samples.

How the data were processed

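The 83 arrays hold 612 spots each: 438 spots of 146 dsrAB probes (3 spots per probe), 72 spots of 12 control probes named dsrCONT (6 spots each), 78 DMSO blanks, 6 spots named Cont and 18 spots without a name. What the dsrCONT spots control is not stated in the sources used here, and dsrCONT5 and dsrCONT6 stayed near background (median ratios 0.98 and 0.99), so scaling to these spots takes them as equal between arrays by assumption. The arrays were of 1 colour, with RNA labelled with Cy3 by in vitro transcription, per the labels' protocols. The deposited values are intensity values: the median pixel brightness of each spot and of its local background, measured at 532 nm on a GenePix 4100A scanner with GenePix Pro 5.1.0.19 and not normalized, per the file headers. The percent of saturated pixels per spot is also given, per the file headers, and 0.036% of the probe spots had any. Spots that the files flag as not found were kept and could count as detected. On peat arrays of scan run I they numbered 0 to 411 of the 612 spots, against 0 on peat arrays of runs J and K. The median local background of an array ran from 144.5 to 521 on peat arrays and from 77 to 421 on clone arrays, and the median ratio of the dsrCONT spots from 20.2 to 87.8 and from 8.62 to 111.9. Groups, layers, years and cores were taken from the labels. No map from probes to organisms and no reference genome was used here.

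A probe's ratio is the spot's foreground over its local background, averaged over its 3 spots, and a ratio of at least 2 counted as detected. A clone's list holds the probes detected on its array with at least 10% of the background-subtracted signal of its brightest probe. Lists of at least 3 tested probes were used in set tests, which left 20 clones, and lists sharing over 80% of the smaller list formed 1 family, which joined 11c_20 with dsr9 and 34_40 with dsr54. The lists come from the clone arrays, not from the peat they were tested on.

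Peat intensities were corrected with normexp (offset 50), quantile normalized over the 41 peat arrays, transformed to log2 and averaged over the 3 spots of a probe in limma 3.58.1 (R 4.3.3). Tests used the 96 probes detected on at least 3 peat arrays, of which 86 belong to a clone list. Slopes on mid-depth per 10 cm, the interaction of depth with year and differences of core means between years were fitted with lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment at 0.05. The main fits of slopes and of the interaction held no term for the core, so layers of 1 core counted as separate arrays. The core as a block was an alternative. Quantile normalization gives every array the same distribution, so a slope is relative to the other probes of the array. Slopes and tests use the measured values of all arrays. Where a probe was detected on no array of a group, the difference between groups is given as at least N-fold, from the brighter group's mean log2 value and, on each array of the dimmer group, the higher of the probe's own value and the lowest value of a detected tested probe. These folds are of quantile-normalised values, so they too are relative to the other probes and give no lower bound for unscaled brightness. Lists were tested with fry and with camera at a preset correlation of 0.01 and at an estimated one; fry asks whether a list's probes move one way on balance, and does not compare them with other probes. Detected probes were tested by permuting depths within cores, and years by permuting cores. Bray-Curtis dissimilarity was computed on each array's shares of the total background-subtracted signal, with layers permuted within cores. Permutation tests were exact up to 100000 arrangements and used 100000 resamples beyond. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for these.

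The limma code was tested on simulated data with 30 of 96 probes changed. With a 2-fold change per 10 cm it recovered 30 of 30 for 2001, 0 for 2004 and 23 for 2007, and with a 4-fold change 30, 19 and 30. Unchanged probes called for these years numbered 2, 0 and 2 at 2-fold and 2, 1 and 3 at 4-fold. For the 3 years in the upper 10 cm the code recovered 0 at 2-fold and 12 at 4-fold, with 0 unchanged probes called at either.

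The comparisons, tests, lists and the rule for naming probes were set before the data were examined. The rule took, per limma comparison, the 10 probes with the largest positive and the 10 with the largest negative coefficient among those passing, and the 5 with the smallest p not passing where fewer than 10 passed; the 10 most often detected probes for the core set; all probes of the dsr36 list; and the clones with most or fewest probes, where ties made 5 clones share the fewest. The probe dsrA109 on the clone arrays was named after its values were seen.

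Cores carry letters A, B and C. Layers of 1 letter within a year come from 1 core per the labels, and deviations from the layer mean correlated at a median of 0.518, 0.065 and 0.518 in 2004 and 0.473, 0.339 and 0.261 in 2007, against 0.103, -0.054 and 0.068 in 2001. The same letter in 2004 and 2007 gave -0.529, -0.139 and -0.162, so a letter does not pair cores across years. Counts from fits with the core as a block had been seen before this check was made, and its criterion was applied as it stood.

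Alternatives covered the detection threshold, background correction, scaling between arrays, the filter on dim probes, cores left out in turn, the core, scan run and slide as blocks, the definition of lists and the dissimilarity measure. Added after the data were examined were scaling to the dsrCONT spots, slide as a random block, fits within scan runs, averaging of the 2001 layers, the dsrCONT ratio as a covariate, and leaving out 4 doubted arrays: core B at 0 to 5 cm of 2004, which detected 1 probe; core C at 0 to 5 cm and core A at 15 to 20 cm of 2007, whose image names carry the word bad; and core A at 5 to 10 cm of 2007, whose image shares the sample number 51 with core A at 0 to 5 cm. The array labelled clone 4_40 has an image named for clone 14_40. No probe was detected on both that array and the array labelled 14_40, which does not tell which of them is 14_40. Both are used as labelled, so results for the list of 14_40 carry this doubt. The series' design text counts 33 environmental hybridisations, where 41 peat arrays and 6 spike-in arrays were analysed here; the 4 layers of 2001 and the 12 and 17 peat arrays of 2004 and 2007 make 33.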

Results

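The dsrA and dsrB genes encode the subunits of dissimilatory (bi)sulfite reductase, the enzyme that sulfate-reducing microorganisms use to make sulfide, and they serve as marker genes for these organisms in soil. Oligonucleotide microarrays carrying 146 probes for such genes, 128 for dsrA and 18 for dsrB, were hybridised with Cy3-labelled RNA transcribed in vitro from dsrAB PCR products. Of the 83 arrays, 36 each received 1 cloned dsrAB sequence, 6 received peat soil DNA with rising copy numbers of the clone dsr36, and 41 received peat soil from 3 sampling years. The peat arrays covered 4 layers between 0 and 30 cm in 2001 (12 arrays), 4 layers between 0 and 20 cm in 2004 (12 arrays) and 6 layers between 0 and 40 cm in 2007 (17 arrays). A probe was counted as detected where its signal was at least 2 times its local background, averaged over its 3 spots. Blank spots reached that ratio 6 times among 6474. Probes are given by their names on the array, since the sources used here pair them with no organism. The number of arrays limits the precision of every comparison.

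The labels place the arrays of each layer in cores A, B and C. In 2001 the image names of the 12 arrays carried 4 sample numbers, 1 per layer. In 6 of these names the number was followed by a letter that matches core B or C, and in 2 names of those cores it was not. The arrays of a 2001 layer correlated at 0.915 to 0.992 over the tested probes. Within layers of 2004 and 2007 the correlations ran from 0.391 to 0.791. The p-values for 2001 measure the spread between those arrays, which may be technical. Values with each 2001 layer averaged to 1 sample stand beside the results they change, except for the set tests, which were not run on averaged layers.

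The clone arrays addressed which probes each known dsrAB sequence lights. A clone lit between 3 and 14 probes, with a median of 6. The clone 11c_20 lit 14 probes, most brightly dsrA75 at 118 times background. The clone dsr60 lit 12 probes, led by dsrA3 at a ratio of 220.0, and 3c_20 lit 11, led by dsrA78 at 43.7. The fewest probes, 3 each, were lit by 12_20, 4_40, dsr39, dsr88 and dsr3-1-1, whose brightest probes were dsrA103, dsrA27, dsrA86, dsrB120 and dsrB130. None of the probes lit by these 5 clones was lit by another clone. The probe dsrA109 was the least specific and was lit by 17 clones. Of all 5256 pairs of clone and probe, 223 were above the threshold, which is 4.24%. In all, 122 probes were lit by at least 1 clone, 84 of them by 1 clone alone, and 24 by none. There was 1 array per clone, so these values have no replicate error, and with a ratio of 1.5 as the threshold the median rose to 10 probes per clone.

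The spike-in arrays addressed how few copies of a sequence the array can find in peat. The clone dsr36 has a list of 6 probes. Of these, dsrB67, dsrA64 and dsrA63 were already detected at 1 added copy, with ratios of 2.42, 2.24 and 2.99, so their lowest detectable amount cannot be separated from sequences in the peat itself. The probes dsrB65 and dsrB66 were detected from 100 copies upward and dsrA70 from 1000 copies, so the lowest limit free of that was 100 copies. The median log2 signal of the list rose from 6.81 at 1 copy to 8.30, 9.08, 10.52, 14.50 and 15.14 at 10, 100, 1000, 10000 and 100000 copies. The signal followed the logarithm of the copy number (Pearson's r = 0.971, exact permutation p = 0.00278, and Spearman's rho = 1.0, exact permutation p = 0.00278, the smallest that 6 doses can give, two-sided). Without the lowest and highest dose r was 0.938. The 63 other probes detected at all doses gave r = -0.54 (exact permutation p = 0.261) and rho = -0.657 (exact permutation p = 0.175), and r = -0.94 without those 2 doses. Each dose had 1 array, and that limit was 10 copies with a threshold ratio of 1.5. With a ratio of 3 only dsrA63 and dsrA64 passed at 10 copies, which may owe to sequences in the peat, while dsrB65 passed from 1000 copies and dsrB66 and dsrA70 from 10000.

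**Figure D1:**
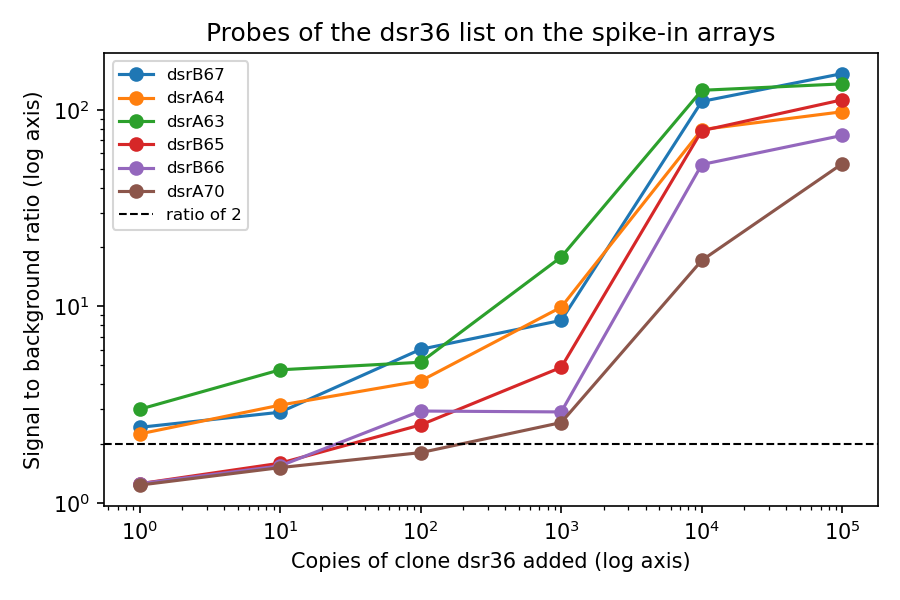
Signal to background ratio (log axis) of the 6 probes of the clone dsr36 list against the copies of that clone added to peat (log axis), with 1 array per dose and a dashed line at the detection ratio of 2. The probes dsrB67, dsrA64 and dsrA63 lie above 2 at 1 copy, and dsrB65 and dsrB66 pass it at 100 copies.

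The series' title speaks of a core microbiota, and the peat arrays show which probes recurred. The probes dsrA138 and dsrA11 were each detected on 40 of the 41 peat arrays, with median ratios of 12.8 and 9.91. They were followed by dsrA3 and dsrA72 on 39 arrays, with median ratios of 17.6 and 16.7, by dsrA78 and dsrA137 on 37, and by dsrA71, dsrA75, dsrA73 and dsrA77 on 36. Of these 10 probes, dsrA71, dsrA72, dsrA73, dsrA75, dsrA77 and dsrA78 belong to the list of clone dsr9. No probe was detected on all 41 arrays, a count of 0 that comes from detection with no test behind it, so no unadjusted p exists. The array of core B at 0 to 5 cm in 2004 detected 1 probe, and without it 2 probes, dsrA138 and dsrA11, were detected on all 40 others. By year, 9 probes were detected on all arrays of 2001, 0 on all of 2004, or 4 without that array, and 4 on all of 2007. Across the peat 113 probes were detected at least once, 19 on at least 30 arrays and 33 on none.

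The number of detected probes rose with depth in every year. In 2001 it went from 19.3 ± 9.45 (SD, n = 3) at 0 to 10 cm to 70.0 ± 6.24 (SD, n = 3) at 17.5 to 25 cm and 57.0 ± 8.89 (SD, n = 3) at 25 to 30 cm. In 2004 it went from 16.0 ± 13.2 (SD, n = 3) at 0 to 5 cm to 52.7 ± 9.02 (SD, n = 3) at 15 to 20 cm. In 2007 it went from 16.7 ± 5.86 (SD, n = 3) at 0 to 5 cm to 59.0 ± 15.7 (SD, n = 3) at 15 to 20 cm, with 49.5 ± 2.12 (SD, n = 2) at 30 to 40 cm. The slope within cores was 20.0 ± 4.38 (SE) probes per 10 cm in 2001 (exact permutation p = 0.00383, adjusted over the 3 years 0.00657), 23.3 ± 6.43 in 2004 (exact permutation p = 0.00984, adjusted 0.00984) and 10.4 ± 3.20 in 2007 (permutation p = 0.00438, adjusted 0.00657), two-sided, and was positive in 3 of 3 cores each year. Within single scan runs the slope was 18.8 (exact permutation p = 0.0556) and 21.9 (p = 0.0278) in 2001, 25.4 (p = 0.0125) in 2004, and 11.3 (permutation p = 0.0231) and 10.5 (exact p = 0.1) in 2007; the remaining runs held too few arrays or 1 layer. With each 2001 layer averaged to 1 sample the slope kept its size with an exact permutation p of 0.125, where the 24 orders of 4 layers can give 0.0417 at the smallest. The exact permutation p was 0.066 without core A and 0.111 without core B in 2004, where the slope without core B was 14.7, and the permutation p was 0.0505 without core C in 2007.

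**Figure D2:**
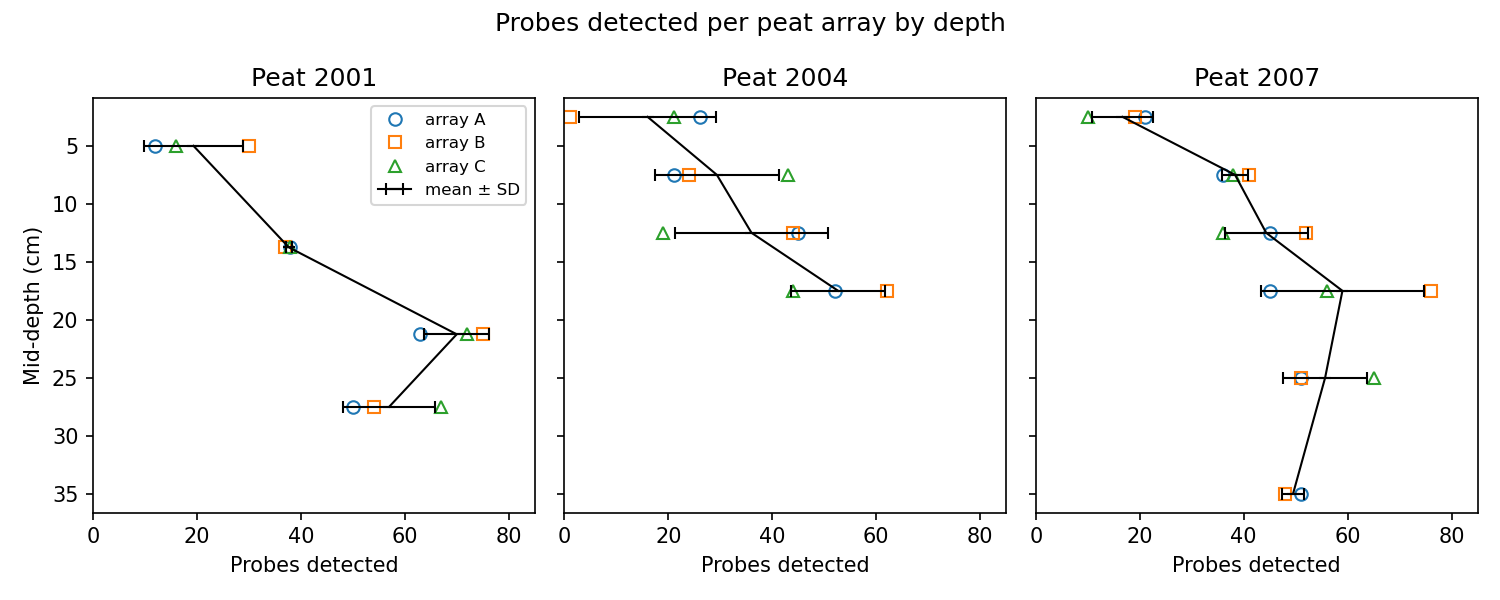
Probes detected per peat array (horizontal axis, of 146) against the mid-depth of the layer in cm (vertical axis), 1 panel per year; open symbols are the arrays of cores A, B and C, and bars are the mean ± SD of a layer. Means run from 19.3 to 70.0 in 2001, from 16.0 to 52.7 in 2004 and from 16.7 to 59.0 in 2007.

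In the upper 10 cm, which all years share, the number of detected probes was 19.3 ± 9.45 in 2001, 22.7 ± 9.78 in 2004 and 27.5 ± 3.12 in 2007 (SD, n = 3 cores each). No difference among the years was found (exact permutation p = 0.529 over 280 arrangements), which with 3 values per year does not show that there was none. The 2001 arrays may be repeats of 1 sample, so their SD may be technical. They also come from 1 layer of 0 to 10 cm, while 2004 and 2007 values are means of the layers 0 to 5 and 5 to 10 cm.

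In the peat of 2001, dsrA83 and dsrA85, both lit by clone 10_05, fell with depth. The brightest probe of that clone, dsrA84 at a ratio of 232.05 on the clone array, was detected on 1 of the 12 arrays and was not tested. The probes dsrA83 and dsrA85 were detected on 3 of 3 arrays at 0 to 10 cm and on 0 of 3 at 25 to 30 cm, where they were not well above background. In quantile-normalised values the top layer was thus at least 37.9-fold brighter for dsrA83 and at least 35.2-fold for dsrA85 (limma adjusted p for the slopes 1.28e-08 and 1.87e-08). Such folds depend on the scaling. The median slope of the 21 probes called falling was -1.05 with quantile normalisation and -0.12 without scaling. It was -0.24 with the dsrCONT spots, -0.99 with median and -1.50 with total scaling. The probes dsrA63, dsrA64, dsrB67, dsrB66 and dsrB65 of the clone dsr36 list rose together, from 0 of 3 arrays at 0 to 10 cm to 3 of 3 at 25 to 30 cm, and the deepest layer was at least 2.96-fold brighter for dsrA63, 2.04-fold for dsrA64 and 2.18-fold for dsrB67. Fitted slopes take the measured value of a probe also where it was not above background. They were -2.88 ± 0.16 (SE) log2 units per 10 cm for dsrA83, -2.76 ± 0.17 for dsrA85, 2.85 ± 0.45 for dsrA63, 2.66 ± 0.41 for dsrA64, and 2.39, 2.09 and 2.06 for dsrB67, dsrB66 and dsrB65. Other named probes that rose were dsrA102 (2.21), dsrA69 (1.77), dsrA90 (1.72), dsrA96 (1.64) and dsrA79 (1.62). Named probes that fell were dsrA52 (-2.03), dsrA15 (-1.77), dsrA39 (-1.69), dsrB130 (-1.55), dsrA129 (-1.47), dsrA11 (-1.17), dsrA55 (-1.17) and dsrA109 (-1.06). Of these 8, dsrA52 and dsrA15 were also called without scaling and with scaling to the dsrCONT spots, as were dsrA83 and dsrA85, while the other 6 were called under neither, and dsrA11 (0.02) and dsrA109 (0.06) had slopes above 0 without scaling. But dsrA15 and dsrA55 were each detected on 1 of the 12 arrays, so their slopes rest mostly on values not well above background. At 0 to 10 cm dsrB130, dsrA129 and dsrA109 were detected on 1 of 3 arrays each. They were detected on 3 of 3 at 17.5 to 25 cm, and on 0, 0 and 2 of 3 at 25 to 30 cm. Of the 10 named rising probes, dsrB66, dsrB65, dsrA90 and dsrA96 were not called with total scaling, nor dsrA90 with median scaling. In all, limma called 56 of 96 tested probes at an adjusted p under 0.05 on 12 arrays, 35 rising and 21 falling, and 49 of the 86 probes that belong to a clone list passed when adjusted over the list alone.

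With each 2001 layer averaged to 1 sample, 2 of those 56 probes passed in limma, dsrA83 and dsrA85 (both adjusted p = 0.0342), beside 28 at an unadjusted p under 0.05. The balance of rising and falling probes depended on the scaling between arrays. Quantile normalisation left a median slope of 0.09 log2 units per 10 cm over all tested probes and 35 rising against 21 falling, while no scaling gave 0.68 and 40 against 4, scaling to the dsrCONT control spots 0.56 and 39 against 4, median scaling -0.20 and 26 against 31, and total scaling -0.70 and 14 against 44. Within single scan runs 45 and 26 probes passed. The set tests took the 12 arrays as separate samples and were not run on averaged layers, so their calls may rest on technical spread. In the set test fry 17 of 20 clone lists moved one way, 9 up and 8 down, among them dsr36 (6 of 6 members rising, median 2.24), 46c_20 (5 of 5 rising, median 2.39, with 4 of its 5 probes shared with dsr36) and dsr3-1-1 (3 of 3 falling, median -1.47). The competitive test camera with a preset correlation called those 3 lists, and with an estimated correlation no list passed (lowest adjusted p = 0.378 with an estimated correlation).

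**Figure D3:**
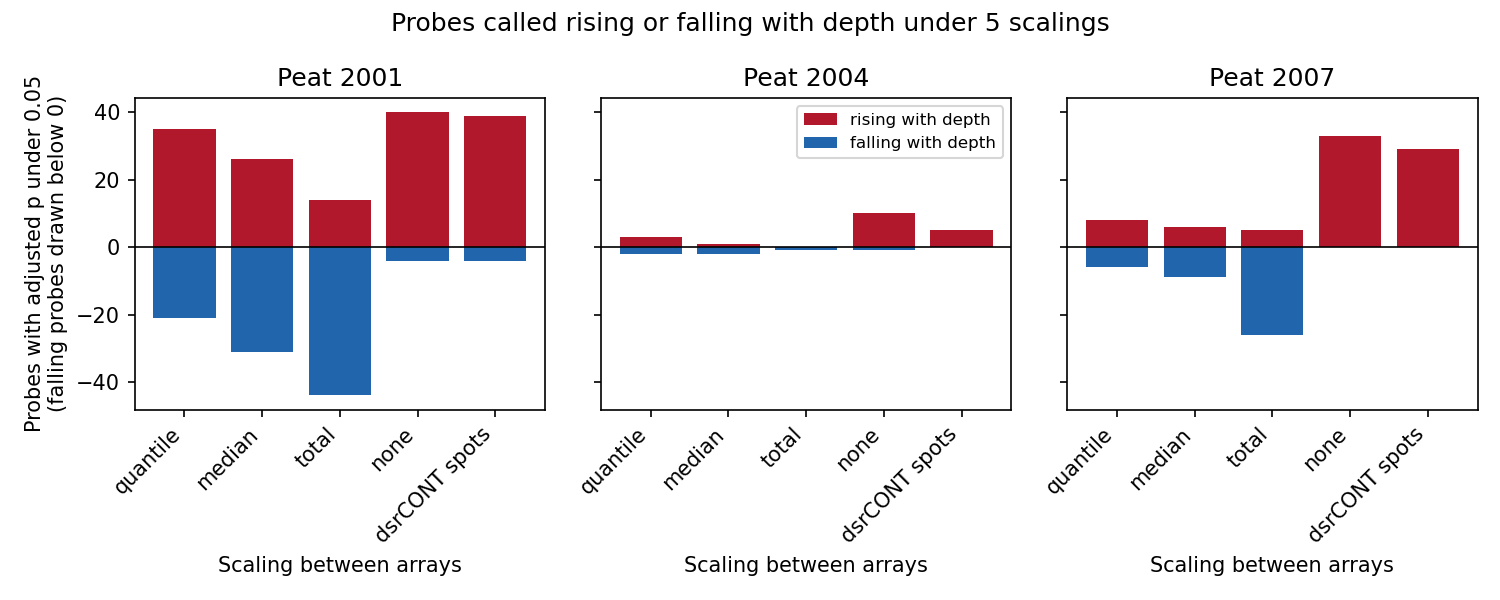
Number of probes with a limma adjusted p under 0.05 that rose (red, above 0) or fell (blue, below 0) with depth in each year, under 5 scalings between arrays. In 2001 the split is 35 to 21 with quantile normalisation, 14 to 44 with total scaling and 39 to 4 with scaling to the dsrCONT spots.

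In the peat of 2004, dsrA15 fell by 4.05 ± 0.52 (SE) log2 units per 10 cm (limma adjusted p = 0.000238, 12 arrays), and was detected on 2 of 3 arrays at 0 to 5 cm and on 1 of 3 at 15 to 20 cm. The probe dsrA115, of clones 14_40 and dsr82, had a slope of -1.90 ± 0.47 (adjusted p = 0.0283), but its detection did not fall. It was detected on 1 of 3 arrays at 0 to 5 cm, 3 of 3 at 5 to 10 and at 10 to 15 cm, and 2 of 3 at 15 to 20 cm. The probes dsrA124 and dsrA122, both of clone 15d_20, rose by 2.31 ± 0.48 (adjusted p = 0.0155) and 1.60 ± 0.37 (adjusted p = 0.0261), and dsrA53 rose by 1.92 ± 0.48 (adjusted p = 0.0283). These 3 were detected on 0 of 3 arrays at 0 to 5 cm, where they were not well above background, and on 3 of 3 at 15 to 20 cm. These 5 of 96 probes passed in limma, 3 rising and 2 falling, with 11 at an unadjusted p under 0.05 and 3 when adjusted over the list alone. The probes with the next smallest p, which did not pass, were dsrA109 at -1.91 (adjusted p = 0.052), dsrA102 at 1.64 (0.052), dsrA87 at 1.69 (0.0965), dsrB117 at -1.70 (0.109) and dsrA143 at 2.27 (0.239). The list of 15d_20 moved up in fry (adjusted p = 0.0134), with 2 of 3 members called rising and dsrA123 at 0.69 not called. In camera it passed with a preset correlation together with 14_40 and dsr82, both downward and sharing 2 probes, dsrA115 and dsrB117. None passed in camera with an estimated correlation (lowest adjusted p = 0.321 with an estimated correlation). The calls rested on few arrays: 1 probe, dsrA15, passed without core A or without core B, 2 within run J, 3 with scan run as a block and 3 without the array of core B at 0 to 5 cm. All 3 arrays of the 10 to 15 cm layer were in run I, which held no other layer of 2004. That layer cannot be told apart from its run. Without core C the 3 rising probes were not called (adjusted p = 0.0746 for dsrA124), and the 4 called were the falling dsrA15, dsrA115, dsrA109 and dsrB117. The split was 10 rising against 1 falling without scaling, 5 against 0 with the dsrCONT spots, 1 against 2 with median and 0 against 1 with total scaling, and the median slope of all probes was 0.20, 0.90, 0.90, -0.10 and -0.54 with quantile, no, dsrCONT, median and total scaling; dsrA15 kept a negative slope in all of these, at -1.94 (adjusted p = 0.0793) with the dsrCONT spots. The probe dsrA115 was called with quantile normalisation alone, dsrA53 and dsrA122 were not called with median scaling, and of the 5 only dsrA15 was called with total scaling.

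In the peat of 2007, dsrA15 fell by 1.20 ± 0.37 (SE) log2 units per 10 cm with quantile normalisation, going from 13.40 at 0 to 5 cm to 8.21 at 10 to 15 cm and 9.01 at 30 to 40 cm, but its slope was -0.20 without scaling and -0.28 with the dsrCONT spots. The probes dsrB117 (-0.87), dsrA1 (-0.74) and dsrA115 (-0.73) had falling slopes as well, without a matching fall in detection. They were detected on 2, 1 and 1 of 3 arrays at 0 to 5 cm and on 2, 3 and 2 of 3 at 20 to 30 cm. At 30 to 40 cm it was 1, 2 and 0 of 2. The probes dsrA83 (-0.75) and dsrA85 (-0.38) also passed, but were detected on 1 and 0 of the 17 arrays, so these slopes lie in values not well above background and show no fall of a measured signal. The probes dsrA30 at 0.94 ± 0.14, dsrA79 at 0.90 ± 0.21, dsrA59 at 0.88 ± 0.21, dsrA125 at 0.80 ± 0.24, dsrA58 at 0.77 ± 0.19, dsrA74 and dsrA78 at 0.69 and dsrA34 at 0.50 rose with depth, dsrA58 and dsrA59 both belonging to clone dsr40. Of these, dsrA30, dsrA125 and dsrA34 were detected on 5, 4 and 2 of the 17 arrays, on none of them at 0 to 5 cm. The probe dsrA34 was also detected on 0 of 2 arrays at 30 to 40 cm, so its slope shows no rise of a measured signal. Only dsrA79 and dsrA78 were called under all 5 scalings: dsrA30, dsrA59, dsrA125, dsrA58 and dsrA34 were not called with median or total scaling nor dsrA74 with total scaling, under which dsrA34 had a slope of -0.07. In all, limma called 14 of 96 probes on 17 arrays, 8 rising and 6 falling, with 26 at an unadjusted p under 0.05 and 13 when adjusted over the list alone. In fry the lists of 3c_20 and dsr40 moved up and those of 14_40 and dsr82 down (lowest adjusted p = 0.0296), and 7 lists passed with the core as a block, but no list passed in camera with an estimated correlation (lowest adjusted p = 0.528). The preset camera called 11c_20 and 3c_20 upward and 14_40 and dsr82 downward. The lists of 14_40 and dsr82 share 2 probes, dsrA115 and dsrB117, and those of 11c_20 and 3c_20 share 3, so these are not separate results. Of the other tested members, dsrA109 of 14_40 had a slope of -0.74. The slopes of dsrA110 of 14_40 and of dsrB118 and dsrA116 of dsr82 were -0.03, -0.13 and -0.17. None of these passed in limma. With the core as a block 14 probes passed as well, 12 of them shared, and dsrA15 and dsrA115 were not called (both adjusted p = 0.0503).

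The 2007 count was sensitive to single cores. It was 0 without core B (22 at an unadjusted p under 0.05 in limma), where the slope of dsrA125 was 0.27, 6 without core A, 4 without core C, and 2 without the 3 arrays of that year whose image names raised doubts. Within scan runs I and J it was 1 and 0 (23 and 15 at an unadjusted p under 0.05), with fewer arrays, and all 14 slopes kept their direction in both. Calls depended on the scaling: none of the falling probes was called, and 33 and 29 probes rose, without scaling and with the dsrCONT spots, while median scaling gave 6 rising against 9 falling and total scaling 5 against 26. The median slope over all probes was 0.08, 0.54, 0.46, -0.08 and -0.23 with quantile, no, dsrCONT, median and total scaling. Under the unscaled values dsrB117, dsrA1 and dsrA115 had slopes above 0.

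With quantile normalisation dsrA15 and dsrA115 were the 2 probes called in both 2004 and 2007, falling in each, but dsrA115 had a 2007 slope of 0.15 without scaling and 0.07 with the dsrCONT spots. With the core as a block neither of these 2 was called in 2007. No scaling and the dsrCONT spots called 5 and 3 other probes in both years, all rising, median scaling 1 other, and total scaling dsrA15 alone. In 2001 and 2007 together 11 probes were called, all in the same direction, against 9 of 11 with median and 15 of 16 with total scaling, and in 2001 and 2004 together 4 were called, all in the same direction. The 11 include dsrA83 and dsrA85, whose 2007 signal was not well above background, and dsrA15, detected on 1 of the 12 arrays of 2001. With the 2001 layers averaged dsrA83 and dsrA85 are the only calls of 2001, so no shared call of a measured signal is left. Averaging left 4 samples and did not change the slopes, as for dsrA15 at -1.77 and dsrA79 at 1.62 (both limma adjusted p = 0.111). Whether slopes differed between 2004 and 2007 was tested over the 4 layers of 0 to 20 cm on 24 arrays. No probe passed in limma (0 of 96, 1 at an unadjusted p under 0.05, smallest adjusted p = 0.894). The smallest p-values, none passing, belonged to dsrA88 (a slope difference of 1.37 ± 0.58), dsrA128 (-1.54 ± 0.79), dsrA83 (-1.60 ± 0.86), dsrA124 (-1.22 ± 0.67) and dsrA129 (-1.79 ± 1.02, but 1.27 within run J). The lists of dsr3-1-1, 34_40 and dsr54, the last 2 sharing probes as 1 family, were lower in 2007 by the preset camera, but not by fry (lowest adjusted p = 0.815) or by camera with an estimated correlation (adjusted p = 0.709). In simulated data of this design, 3 of 30 probes with a 2-fold and 13 of 30 with a 4-fold slope difference were recovered, beside 0 and 2 unchanged probes called.

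The years 2004 and 2007 were compared over 0 to 20 cm on means of 6 cores. No probe passed in limma (0 of 96, 5 at an unadjusted p under 0.05, smallest adjusted p = 0.69). The 5 probes with the smallest p, none passing, were dsrA129 at 1.70 ± 0.55 (SE, but -0.79 within run J), dsrA86 at 2.07 ± 0.81 and dsrA88 at 1.12 ± 0.48 log2 units for 2007 minus 2004, and dsrA75 at -1.21 ± 0.47 (but 0.51 within run I) and dsrA78 at -1.01 ± 0.42. The lists of 11c_20 and dsr9, which hold dsrA75 and dsrA78, were lower in 2007 by the preset camera, as were 3c_20, which holds dsrA78, and 15d_20, while dsr3, dsr3-1-1 and dsr39 were higher. None of these held in fry (lowest adjusted p = 0.286) or in camera with an estimated correlation (lowest adjusted p = 0.424). In simulated data of this design, 2 of 30 probes with a 2-fold and 25 of 30 with a 4-fold change were recovered, beside 1 unchanged probe called in each case.

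Across all 3 years in the upper 10 cm, dsrA85 and dsrA83 of clone 10_05 stood far higher in 2001, where both were detected on 3 of 3 arrays. The brightest probe of that clone, dsrA84, was detected on 1 of the 12 arrays of 2001 and was not tested. The result thus covers dsrA85 and dsrA83, not the whole list of the clone. In 2004 and 2007 dsrA85 was detected on 0 of 6 arrays each, not well above background, so it was at least 5.96-fold and at least 8.48-fold brighter in 2001. These folds and those that follow are of quantile-normalised values. The probe dsrA83 was at least 6.41-fold brighter in 2001 than in 2004 (0 of 6 arrays), and in 2007 it was detected on 1 of 6 arrays. The probe dsrA143, of clone 25c_40, went the other way, detected on 0 of 3 arrays in 2001, 2 of 6 in 2004 and 4 of 6 in 2007, which was at least 1.30-fold brighter than 2001. These 3 of 96 probes passed limma's F-test on 9 core means (adjusted p = 5.54e-06 for dsrA85, 0.000255 for dsrA83 and 0.0383 for dsrA143), with 15 at an unadjusted p under 0.05 and 3 when adjusted over the list alone. The next probes, which did not pass, were dsrA39, dsrA86, dsrA75, dsrA52 and dsrB81 (adjusted p = 0.0652 to 0.119). With the 2001 layer averaged to 1 sample, which is then assumed to vary like the other years, 1 probe passed, dsrA85. Of the 96 probes 6 passed without the doubted arrays, 2 without core letter B and 5 without core letter C. The probe dsrA143 was not called under median, total, dsrCONT or no scaling or without any 1 core letter, and within run J no probe passed (0 in limma, 5 at an unadjusted p under 0.05), with fewer arrays and measured differences no smaller for dsrA85 and dsrA83 (both adjusted p = 0.0693). Run I held 0 of the 12 arrays of 2001 and 11 of the 17 arrays of 2007, so year and scan run are partly confounded. Other assignments of the cores to years gave up to 8 probes. No clone list passed fry (lowest adjusted p = 0.447 for 2004 minus 2001 and 0.291 for 2007 minus 2001), and dsr9, lower in 2007 than in 2001 by the preset camera, had an adjusted p = 0.775 with an estimated correlation.

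The whole probe profile was compared by Bray-Curtis dissimilarity, which runs from 0 for identical shares to 1. Arrays of a 2001 layer differed by 0.132 ± 0.053 (SD) on average and arrays of different layers by 0.435 ± 0.126. In 2004 the means were 0.595 within and 0.565 between layers, and in 2007 they were 0.506 and 0.515. Layer accounted for 91.5% of the variation in 2001 (exact permutation p = 0.00174, the smallest possible, adjusted over 4 tests 0.00694), 23.8% in 2004 (exact permutation p = 0.026, adjusted 0.0321) and 35.7% in 2007 (permutation p = 0.012, adjusted 0.024). A share of this kind lies above 0 for random layers too, and only the permutation p takes that into account. In 2004 and 2007 arrays of 1 layer were about as unlike as arrays of different layers, so these p-values rest on permuting layers within cores. The 2001 value sets layers against a spread within layers that may be technical, and with each layer averaged to 1 sample no spread is left to test it against. With layers permuted within scan runs the permutation p was 0.0001 in 2001, 0.413 in 2004 and 0.195 in 2007, so no separation of the 2004 and 2007 layers was found within runs. In 2004 run I held 3 arrays, all of 1 layer, and run K held 1, so these could not change layer. The larger p does not show that layers were alike within runs. In 2004 the exact permutation p was 0.0764 without the array of core B at 0 to 5 cm, 0.0833 without core A, 0.292 without core B and 0.25 without core C, and in 2007 the permutation p was 0.289 without core A and 0.0789 without core C. The year accounted for 43.1% of the variation of the upper 10 cm (exact permutation p = 0.0321, adjusted 0.0321), and for 33.9% with the 2001 layer averaged to 1 sample (exact permutation p = 0.429); leaving out core letter A, B or C gave exact permutation p = 0.267, 0.2 and 0.0667, where 0.0667 is the smallest possible.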

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

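The tests of scaling to the control spots and of repeat hybridisations were chosen only after the results were seen.

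One spot of the control probe dsrCONT5 on the array of core B at 20 to 30 cm in 2007 was 14.4 times its background, a signal outside the probes compared; the next highest of all 498 spots of this control was 1.46. Lists of 3 clones differed between 2004 and 2007 in their depth slope by camera with a preset correlation: dsr3-1-1 (adjusted p = 0.0248), 34_40 (adjusted p = 0.04595) and dsr54 (adjusted p = 0.04595), none of which passed with an estimated correlation (adjusted p = 0.709 with an estimated correlation).

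Detected probes rose with depth in all 3 years. Brighter hybridisation or labelling is argued against as far as the dsrCONT spots record it, since with their ratio as a covariate 3 of 3 years kept a positive slope with permutation p under 0.05 (0.0128, 0.00825 and 0.00484). What the dsrCONT spots control is not stated in the sources used here, and strength they do not record stays open. Scan run and gain are argued against by positive slopes in 5 of 5 testable runs and by permutation p of at most 0.0114 with depths permuted within runs, and the doubted arrays are argued against, since 2 of 2 years kept the slope without them (18.6 and 8.94 probes per 10 cm). A change of the dsrAB community with depth stays open as a hypothesis; the amount of template in the PCR, which may also change with depth, was not tested, and for 2001 the slope rests on 4 layers (exact permutation p = 0.125, with 0.0417 the smallest possible).

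Probes whose normalised signal fell with depth could owe that fall to the scaling between arrays, since deeper arrays light more probes and quantile normalisation forces equal distributions. With arrays scaled to the dsrCONT spots the falling probes of 2001 had a median slope of -0.24 log2 units per 10 cm and those of 2007 of -0.11, neither at 0 or above nor below 0 by more than the interquartile half-range of 0.371 and 0.137. Whether these probes fell in amount or only in share cannot be told apart, because no scaling here is known to hold the total constant. Of the 21 falling probes of 2001, 4 were still called falling with the dsrCONT spots, and of the 6 of 2007, 0 were (41 probes at an unadjusted p under 0.05 in limma).

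The arrays of a 2001 layer resembled each other far more than those of later years, with a lowest correlation of 0.915 against a median of 0.651 within layers of 2004 and 2007. This, with 1 image sample number per layer, is consistent with repeat hybridisations of 1 sample per layer, and the 33 environmental hybridisations of the design text equal the 4 layers of 2001 plus the arrays of 2004 and 2007. Against it, the labels name 3 cores, and 6 of the 2001 image numbers carry a letter that matches core B or C, which repeats of 1 sample could carry too. Separate cores with more uniform peat in 2001 were not tested and stay open.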

How the results depend on the processing

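Scaling to the dsrCONT spots, slide as a random block, fits within runs, averaged 2001 layers, the dsrCONT covariate and doubted arrays left out were chosen after seeing the data. Of 214 alternatives to the main results, 147 kept direction and side of the threshold, or a count within 1.5 times; of 1001 for named probes, 776 did, 195 lost their call, 17 gained one and 13 changed sign. The cause was not tested except where fewer arrays or probes explain it. A threshold of 1.5 gave a median of 10 probes per clone and a spike-in limit of 10 copies, and a threshold of 3 a limit of 10 that rests on dsrA63 and dsrA64, near the threshold at 1 copy already. The core set held 2 probes without core B of 2004 at 0 to 5 cm, 3 without the doubted arrays, and 0 to 2 without a replicate letter. The richness slope was 14.7 to 30.5 in 2004 and 7.69 to 12.7 in 2007 without a replicate, 20.0 with averaged 2001 layers, and 18.8 in 2001 and 10.5 in 2007 within run J, where few arrays remain. Layers accounted for 22.7 to 46.3% in 2004 and 44.1 to 53.3% in 2007 without a replicate, 20.2% in 2004 without the doubted array, and 23.8% and 35.7% with layers permuted within runs; years accounted for 48.6 to 63.0% without a replicate and 33.9% with averaged 2001 layers.

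Counts of called probes in 2001, 56, became 17 with probes detected on most arrays, 86 in an F-test over layers, 2 with averaged layers and 26 within run K. Filters on detection, here and below, also change the number of probes tested, which was 96 in the main fits. In 2004, 5 became 3 with background subtracted, 11 without scaling, 3 with median and 1 with total scaling, 0 of probes detected on most arrays (limma, 9 at an unadjusted p under 0.05), 1 to 4 without a replicate, 3 with run as a block, 8 with slide as a random block, 1 in the F-test, 3 without the doubted array and 2 within run J. In 2007, 14 became 8 with background subtracted, 33 without scaling, 31 with total scaling, 29 with the dsrCONT spots, 3 of probes detected on most arrays, 0 to 6 without a replicate, 4 in the F-test, 2 without the doubted arrays, 1 within run I and 0 within run J (limma, 15 at an unadjusted p under 0.05). Among the 3 years, 3 became 8 without a filter, 1 of probes detected on most arrays, 2 to 5 without a replicate, 1 with averaged layers, 6 without the doubted arrays and 0 within run J (limma, 5 at an unadjusted p under 0.05). The slope difference and the 2 years' difference stayed at 0 in limma under all alternatives run, with 0 to 9 and 0 to 17 at an unadjusted p under 0.05.

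With lists of all detected probes, clone lists passing fry numbered 29 in 2001, 3 in 2004, 7 in 2007 and 1 in each contrast of the 3 years. At 25% of the brightest probe 0 passed in 2004, and with probes in no other list 6 passed in 2001 and 1 in 2007. The definition of a list also sets how many lists are tested, which was 20 in the main tests. With the core as a replicate block 7 lists passed in 2007. The block gave 54 probes in 2001, 5 in 2004, 14 in 2007, 0 for the slope difference (2 at an unadjusted p under 0.05 in limma), 0 between 2004 and 2007 (2) and 2 among the 3 years, where the letter pairs no cores across years.

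Signs changed without scaling for dsrA11 (0.0186) and dsrA109 (0.0646) in 2001, dsrB117 in 2004 (0.0642), and dsrB117 (0.0409), dsrA1 (0.119) and dsrA115 (0.151) in 2007; with the dsrCONT spots for dsrB117 in 2004 (0.0666) and dsrA1 (0.0395) and dsrA115 (0.0712) in 2007; and with total scaling for dsrA34 in 2007 (-0.0667). Within runs, dsrA129 changed sign for the slope difference (1.27) and for 2007 minus 2004 (-0.79), as did dsrA75 for the latter (0.51). The planned correction for a nonsense probe was not run, since no spot is named as one. Signals near background limit what the dimmer probes can show.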

Other observations

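The test of slopes across years was written before its result was seen, as were the counts over other splits.

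Depth slopes may share a pattern between years. As a hypothesis this was tested by Spearman's correlation of slopes across the 96 tested probes, which are not independent replicates: it was 0.529 for 2001 and 2004, 0.335 for 2001 and 2007 and 0.483 for 2004 and 2007. The lowest of these, 0.335, passed the bound of 0.3 written beforehand, but without scaling it was 0.171, between the bounds of 0.1 and 0.3, which decides neither way. The other pairs were 0.55 and 0.551 without scaling. Median, total and dsrCONT scaling shift all slopes of a year alike and leave these values as they are, so they add no further test. Whether 2001 and 2007 share a pattern stays open.

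Counts of called probes were set against other arrangements of depths or years. In 2001 the real count was 56 and the highest of the others 3, in 2004 it was 5 against 1, and in 2007 it was 14 against 5, with 1 of 100 arrangements, the real one, as large in each. The counts were thus above those of the other arrangements drawn, and 1 of 100 is the smallest share these can give. In 2001 this treats the arrays of a layer as separate samples. If they are repeats of 1 sample, other arrangements break the repeats apart, so the 2001 count cannot decide. Among the 3 years chance was not excluded, with a real count of 3 and a highest other of 8, reached or passed by 8 of 100 splits. For the slope difference (real 0, highest other 0) and for 2007 minus 2004 (real 0, highest other 1) the splits decide nothing, since any split reaches a real count of 0, here 10 of 10, and 10 splits are too few besides (limma, 1 and 5 probes at an unadjusted p under 0.05).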
